A study of Mus musculus with 10 samples.

How the data were processed

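The series holds 10 hybridisations of mouse RNA on spotted cDNA arrays, with total RNA of a different condition in each channel. Per the labels, the cells were adherent peritoneal exudate cells (PEC) and tumour-associated macrophages (TAM) of C57/6N mice aged 8 weeks, cultured with or without 100 ng/mL LPS for 4 hours, and the TAM were taken 3 weeks after implantation of the tumour. Per the labels, the arrays came from 3 print versions: v1p1 (PEC1), v9p2 (TAM-8, TAM7 and TAM-trial) and v3p6 (the other 6). The authors deposited 1 log ratio per feature and array, used here as log2; the image analysis, background correction, spot filtering, normalization, log base and dyes are not given in the sources used here. Base 2 was taken because the largest absolute value, 11.687, is a ratio of 3297 in base 2 but of 119014 in base e, above the highest value of a 16-bit scanner channel, 65535. The array medians of the deposited log2 values lay between -0.199 and 0.022 and their scaled median absolute deviations between 0.688 and 1.165, so the arrays were near 0 but not on 1 scale, and whether the authors centred them is unknown. Signal intensities of the channels were not used here, so no filter on dim spots was possible. All 9596 features had a value on every array, and filters on missing values changed nothing.

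Features were named with the platform table supplied with the values. Of the 9596 features, 7486 had 1 gene symbol, 483 had several and 1627 had none; features with several or no symbols were kept singly and never named. The Entrez identifiers of 7395 features were matched to the reference table, and 0 symbols needed updating. Features of 1 gene were averaged (631 genes had more than 1), which gave 6795 named genes and 8905 genes or features tested. The features of such genes hardly correlated within an array (r from -0.006 to 0.110), so a mean over features may join spots that measure different things. The features of the named genes with 2, Igfbp4, Vegfa, Igf1 and Prdx2, were tested singly as well.

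Values were read as channel 2 over channel 1 and the 2 arrays with exchanged channels, TAM-2R and TAM1, were turned. The rule, fixed before the data were examined, was to recode them if they correlated below -0.3 with the others of their comparison after turning; none did, and both codings were computed. Also chosen before the data were examined were the tests, the gene lists, the rule for named genes and all alternatives except those on feature position and the gene lists and agreement of comparisons with the other coding of the exchanged arrays, which were added after the data had been seen. The reading of channel 2 over channel 1 was to be turned if 72 NF-kB and interferon genes lay below 0 on the arrays of LPS in PEC, so the direction of these lists there was set by that rule.

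Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 10 arrays, with 1 mean log2 ratio for each of the 4 direct comparisons, 6 residual degrees of freedom and an estimated 3.841 prior degrees of freedom. The difference between the LPS responses of TAM and PEC was a contrast in the same fit. P-values were two-sided and adjusted by the Benjamini-Hochberg method over 8905 genes and features within a comparison, with a threshold of 0.05. SDs are over the arrays of a comparison, and standard errors come from the fit. No pseudocount was needed. A mean over the 2 arrays of LPS in PEC, or of LPS in TAM, holds any gene-specific dye effect, because both arrays had the same channel order. The mean of untreated TAM against PEC holds part of such an effect, because of its 4 arrays only TAM-2R was exchanged.

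Shifts of 29 gene lists were tested with cameraPR on the moderated statistics, with the correlation between genes preset at 0.01, and adjusted over the lists of a comparison; a list needed at least 5 measured genes. The lists were NF-kB inflammatory genes, interferon response, alternative activation, matrix remodelling, angiogenesis and growth factors, chemokines, chemokine and cytokine receptors, the Toll-like receptor and NF-kB pathway, MHC class II, MHC class I, complement and Fc receptors, lysosome, lipid handling, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, heat shock and immediate early genes, ribosomal proteins, antioxidant genes, macrophage identity, peritoneal macrophages, fibroblasts and stroma, endothelial cells, T and NK cells, B and plasma cells, neutrophils, mast cells and eosinophils, epithelial and mesothelial cells, and erythroid cells and platelets. Some genes were in more than 1 list. Alternatives were an estimated correlation and fry, which tests whether the genes of a list move, on balance, one way and does not compare the list with other genes. Counts "adjusted over the list alone" used the p-values of the members only.

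Named genes followed a fixed rule. For each comparison these were the 10 highest and 10 lowest genes with 1 symbol past the threshold and with the same sign on every array, filled to 5 per direction by the smallest p where fewer than 5 passed and given as values that did not pass; up to 4 members past the threshold of each list, or the 2 with the smallest p where none passed and the list was reported; and every measured gene of a panel of 30 macrophage genes, of which 17 were measured. Col1a1, Col1a2 and Sparc were named outside this rule, after their values were seen.

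Alternatives to the main processing were median centring of each array, centring with scaling to 1 median absolute deviation, features tested singly, a loop fit that also uses indirect routes between the conditions, that fit with a dye term or a dye term for each print version, a dye term in the direct fit, each comparison on its own arrays, only the arrays of print v3p6, robust eBayes, an added minimum absolute log2 ratio of 1, the other coding of the exchanged arrays, and leaving out each array in turn. For scaling, the planned limma function gave no usable values on this matrix, so the arrays were centred and then scaled with normalizeMedianAbsValues. Added after the data were seen were the subtraction on each array of the median of each position within groups of 96 consecutive features, of each such group as well, and of positions in the loop fit with a dye term, and the tests of the gene lists and the agreement of untreated TAM against PEC with TAM against PEC with LPS under the other coding of the exchanged arrays.

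The fit was tested on simulated data with the spread of the real arrays, with 200 of 8905 genes changed in each of 5 runs. Changes of 1, 2, 3 and 5 on the log2 scale were recovered for 5.6%, 62%, 89.6% and 99.6% of genes in untreated TAM against PEC, for 0.8%, 12.4%, 62.8% and 93.2% for LPS in PEC, for 1.2%, 14.4%, 63.2% and 91.6% for LPS in TAM, and for 1.2%, 17.2%, 62.4% and 94.4% in TAM against PEC with LPS. Of the calls, 6.1%, 5.4%, 7.6% and 5.2% were false. The simulated noise was independent between genes and arrays, with no dye effect and no dependence on feature position. These rates may therefore not hold for the real arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for preparation, further statistics and figures.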

Results

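Gene expression in mouse macrophages was measured on 10 cDNA arrays of the 2-colour kind, on which the RNA of 2 conditions competes for the same spots. The conditions were peritoneal exudate cells (PEC), used as peritoneal macrophages, and tumour-associated macrophages (TAM), harvested 3 weeks after a tumour was implanted. Both were kept as adherent cells in culture, either untreated or after 4 hours with 100 ng/mL of lipopolysaccharide (LPS), a component of bacterial cell walls that activates macrophages through Toll-like receptor signalling. The mice were 8 weeks old. The arrays fall into 4 groups by the conditions they compared directly: 4 arrays set untreated TAM against untreated PEC (TAM-b, TAM-2R, TAM-3 and TAM-8), 2 set PEC with LPS against untreated PEC (PEC1 and PEC2), 2 set TAM with LPS against untreated TAM (TAM-trial and TAM-16), and 2 set TAM with LPS against PEC with LPS (TAM1 and TAM7). Each array held a value for all 9596 features, and the number of arrays limits the precision of every mean given here. The labels do not state that the arrays of a group came from separate animals or cultures, so the p-values measure only the spread between these arrays, which may be technical.

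Each value is a log ratio of the 2 channels, taken as log2. The labels do not name the dyes, so every direction is likely and not certain. Its basis was that 72 NF-kB and interferon genes had a pooled median log2 ratio of 1.406 on the 2 arrays of PEC with LPS against PEC when channel 2 was read over channel 1, with 61 and 63 of the 72 above 0. TAM-2R and TAM1 had their channels exchanged and were turned to the order of the others. After turning, TAM-2R correlated with TAM-b, TAM-3 and TAM-8 at r between 0.036 and 0.101 across all features, and TAM1 with TAM7 at r = 0.293. Of the 13 genes called in untreated TAM against PEC without TAM-2R, 12 had the same sign on it. Of the 14 called in untreated TAM against PEC without TAM1, 13 had the same sign on TAM1. Of the 14 called there without TAM7, 14 had it on TAM7, which was not exchanged. This test was chosen after the data were seen. For TAM1 it assumes that untreated differences persist with LPS, and it rests on calls that include the turned TAM-2R. The test favours the coding of TAM-2R used here but does not prove it, and it does not settle that of TAM1. The counts with the other coding are therefore given beside those of each comparison. Between 4.4% and 49.1% of the variance of an array followed the place of a feature within groups of 96 consecutive feature numbers, against 0.99% by chance, and the 631 genes with more than 1 feature had features that hardly correlated within an array (r from -0.006 to 0.110).

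**Figure D1:**
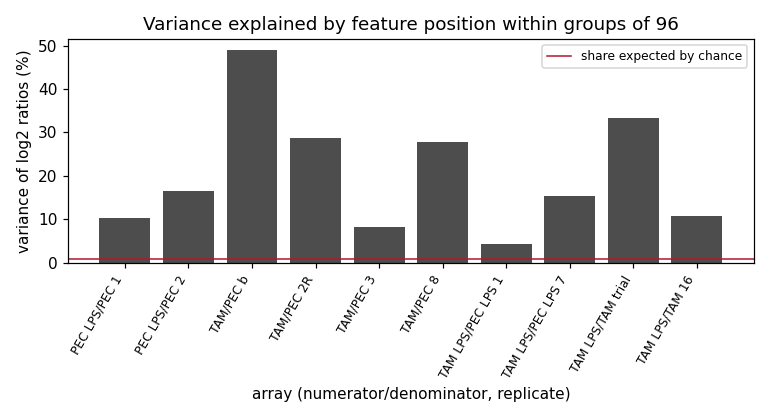
Percent of the variance of the log2 ratios (vertical axis) that followed the place of a feature within groups of 96 consecutive feature numbers, for each of the 10 arrays (bars, horizontal axis), with a line at the share given by chance, 0.99%. It was highest on TAM-b (49.1%) and lowest on TAM1 (4.4%).

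Untreated TAM and PEC differed in 41 of 8905 genes and unnamed features, 11 higher and 30 lower in TAM. The genes lowest in TAM were Saa3, an acute-phase serum amyloid (97.7-fold lower; log2 ratio -6.61 ± 1.05, SD, n = 4, adjusted p = 0.00042), Fcna, which encodes the lectin ficolin A (37.6-fold lower; log2 ratio -5.23 ± 0.93, SD, n = 4, adjusted p = 0.00042), and Retnla, a widely used marker of alternatively activated (M2) macrophages (33.4-fold lower; log2 ratio -5.06 ± 1.26, SD, n = 4, adjusted p = 0.0015). The gene highest in TAM was Cd81, a tetraspanin of the cell surface (10.5-fold higher; log2 ratio 3.39 ± 0.31, SD, n = 4, adjusted p = 0.0013). Their means were -2.80, -2.21, -2.33 and 1.65 with the other coding of both exchanged arrays, and none passed (adjusted p from 0.667 to 0.741). With the coding used here all 4 had the same sign on 4 of 4 arrays, which the rule for naming them required. Their Entrez identifiers were 20210, 14133, 57262 and 12520. This comparison addressed how macrophages of a tumour differ from those of the peritoneum before any stimulus, and the title of the series names an M2 programme in TAM.

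Genes of lipid uptake and transport were lower in TAM. Of the 24 measured genes of the lipid handling list, 4 fell, over all genes as well as adjusted over the list alone. These were the lipase Lpl (log2 ratio -3.85), the fatty acid binding proteins Fabp4 (-3.34) and Fabp5 (-2.93), and the phospholipid transfer protein Pltp (-3.05). Lpl was nearer to 0 on TAM-2R (-2.31) than on the others (-4.51 to -4.25). The list as a whole shifted down (median -0.42, 16 of 24 members below 0, adjusted p = 4.48e-05), and its adjusted p was 0.352 with an estimated correlation. Further genes that fell were Cd5l, a scavenger receptor family protein secreted by macrophages (-3.83, with TAM-b at -0.93 and the others between -5.05 and -4.44), the protease inhibitor Slpi (-4.31), the chemokine Ccl6 (-3.25), the cell surface proteoglycan Sdc1 (-3.21), the urokinase receptor Plaur (-2.36) and the glucose transporter Slc2a1 (-2.13). Their adjusted p-values lay between 0.01 and 0.0352. Retnla was nearer to 0 on TAM-b (-3.18) than on the others (-5.88 to -5.47).

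**Figure D2:**
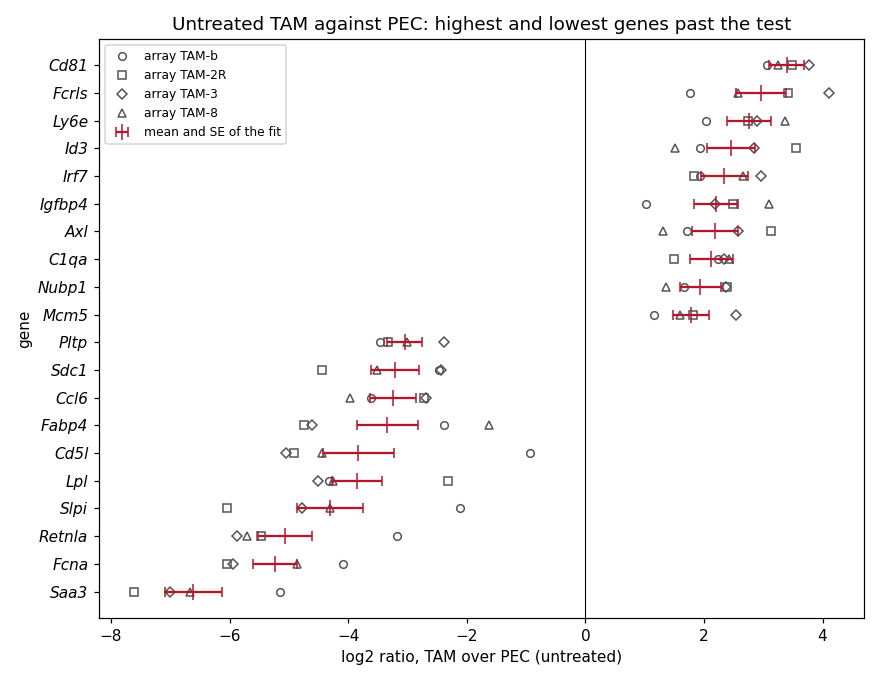
Log2 ratio of untreated TAM over untreated PEC (horizontal axis) for named genes (vertical axis), with a point for each of the 4 arrays, a mark at the mean and a bar for its standard error. Saa3, Fcna and Retnla lay between -7.62 and -3.18 on every array, and Cd81 between 3.07 and 3.78.

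The alternative activation list, which holds genes used to recognise M2 macrophages, shifted down in TAM (median -0.53, 13 of 21 members below 0, adjusted p = 0.0184, and 0.398 with an estimated correlation). Only 21 of the 37 genes of this list were measured, and 11 of the 21 were also in another list. Retnla was its only member past the test over all genes, while 2 members rose and 3 fell when adjusted over the list alone. Mrc1, the mannose receptor, had a log2 ratio of -0.66 ± 0.87 (SD, n = 4, adjusted p = 0.456). The shift of this list rested on TAM-8, without which its adjusted p was 0.0828. The lysosome list also shifted down (median -0.38, 22 of 34 members below 0, adjusted p = 0.0031, and 0.667 with an estimated correlation). Over all genes 2 of its members fell, and 3 when adjusted over the list alone. These included the cathepsins Ctsd (-2.12, adjusted p = 0.0367) and Ctsb (-2.06, adjusted p = 0.0367). Its call was lost without TAM-b (adjusted p = 0.178) and without TAM-8 (adjusted p = 0.0828).

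With the coding used here, inflammatory genes as a group lay lower in untreated TAM, and interferon genes higher. The NF-kB inflammatory list shifted down (median -0.43, 24 of 31 members below 0, adjusted p = 0.000103, and 0.525 with an estimated correlation). Its median was -1.53 on the exchanged array TAM-2R, against -0.55 to 0.01 on the others. Saa3 and Plaur fell over all genes and 3 members when adjusted over the list alone, whereas Tnf, the main inflammatory cytokine of macrophages, had a log2 ratio of -1.15 ± 0.68 (SD, n = 4, adjusted p = 0.33) and Il1b one of 0.62 ± 2.17 (SD, n = 4, adjusted p = 0.734). The interferon response list shifted up (median 0.27, 25 of 41 members above 0, adjusted p = 0.0014, and 0.525 with an estimated correlation). Its call was lost without TAM-3 (adjusted p = 0.0701). Irf7, a transcription factor of the type I interferon response, rose (2.34 ± 0.55, SD, n = 4, adjusted p = 0.0412), as 5 members did when adjusted over the list alone. Cxcl10, an interferon-induced chemokine, had a log2 ratio of 2.66 ± 0.90 (SD, n = 4) and narrowly missed the threshold (adjusted p = 0.0505).

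Other genes that rose in TAM were Fcrls, an Fc receptor-like gene (2.96), the interferon-inducible surface protein Ly6e (2.76), the transcriptional inhibitor Id3 (2.46), Igfbp4, which binds insulin-like growth factors (2.20, with its features singly at 2.19, adjusted p = 0.039, and 2.21, adjusted p = 0.077), the receptor tyrosine kinase Axl (2.18), the complement subunit C1qa (2.12), Nubp1 (1.94) and the DNA replication helicase subunit Mcm5 (1.78), with adjusted p-values between 0.0152 and 0.0451. C1qa was the 1 member of the complement and Fc receptor list past the test over all genes, and 4 of its 14 members rose when adjusted over the list alone. The list shifted up (median 0.26, adjusted p = 0.0203, and 0.569 with an estimated correlation), but not without TAM-2R (adjusted p = 0.106) or TAM-3 (adjusted p = 0.156). The cell cycle list shifted up (median 0.43, 31 of 44 members above 0, adjusted p = 0.000158, and 0.352 with an estimated correlation). Mcm5 rose over all genes, and 8 of its members rose and 2 fell when adjusted over the list alone. On TAM-b the median of this list was -0.28, against 0.55 to 0.68 on the others. The matrix remodelling list shifted down (median -0.43, adjusted p = 0.0242, and 0.525 with an estimated correlation), with Sdc1 and Plaur past the test over all genes and 3 members up and 8 down when adjusted over the list alone. This call was lost without TAM-b (adjusted p = 0.147).

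Of further panel genes given here for untreated TAM, none of the 5 passed the test over all genes. Vegfa, the main angiogenic growth factor, had a log2 ratio of -1.12 ± 0.64 and was lower on 4 of 4 arrays (SD, n = 4, adjusted p = 0.192), with its features singly at -1.41 and -0.83. Mmp9, a protease that degrades matrix, was at 0.82 ± 0.30 and higher on 4 of 4 (SD, n = 4, adjusted p = 0.297). The T cell attractant Ccl5 was at 1.42 ± 0.85, also higher on 4 of 4 (SD, n = 4, adjusted p = 0.221). Tgfb1, an immunosuppressive cytokine, was at 0.59 ± 1.52, and Il12b, a subunit of the cytokine that drives type 1 responses, at -0.00 ± 0.83 (SD, n = 4, adjusted p = 0.688 and 0.998). Both had 2 of 4 arrays above 0, and both turned sign with a loop fit and a dye term (-0.19 and 0.05). The angiogenesis list did not pass (adjusted p = 0.481), and its median (0.14) and mean (-0.15) differed in sign.

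Among markers of cell types that an adherent harvest could hold, the peritoneal macrophage list shifted down (median -0.44, 9 of 14 members below 0, adjusted p = 3.55e-05, and 0.569 with an estimated correlation). Saa3 and Slpi were its members past the test over all genes, and 1 member rose and 5 fell when adjusted over the list alone. The fibroblast and stroma list shifted up (median 0.42, 31 of 42 members above 0, adjusted p = 0.000321, and 0.352 with an estimated correlation). Igfbp4 was its 1 member past the test over all genes, and 7 rose and 2 fell when adjusted over the list alone. The neutrophil list shifted up (median 0.82, 8 of 12 members above 0, adjusted p = 0.0184, and 0.569 with an estimated correlation), with none of its members past the test over all genes by limma and 4 when adjusted over the list alone. S100a9, a calcium-binding protein of neutrophils, was at 1.92 ± 1.29 and Ngp, a granule protein, at 2.50 ± 2.56 (SD, n = 4, adjusted p = 0.122 and 0.221). Ngp was at 6.21 on TAM-3 against 0.56 to 2.12 on the others. The call of the neutrophil list was lost without TAM-3 (adjusted p = 0.4) and without TAM-b (adjusted p = 0.0516). The macrophage identity list did not pass the test (median -0.41, adjusted p = 0.585), nor did the lists of endothelial cells (adjusted p = 0.71), T and NK cells (0.856), B and plasma cells (0.557), mast cells and eosinophils (0.435), epithelial and mesothelial cells (0.129) or erythroid cells and platelets (0.416).

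The count of 41 came from limma with Benjamini-Hochberg adjustment, and 1274 genes had an unadjusted p under 0.05. The count fell to 26 with a loop fit and a dye term, 17 with a dye term added to the direct fit, 10 with the arrays scaled, 9 with a dye term for each array print, 2 on its own 4 arrays, 0 within print v3p6 (3 arrays; 513 at an unadjusted p under 0.05) and 0 with the other coding of the exchanged arrays (744 at an unadjusted p under 0.05). It was 6 without TAM-8, 13 without TAM-2R, 19 without TAM-3, 23 without TAM-b, 24 without TAM-trial or TAM-16, and 14 without any 1 of PEC1, PEC2, TAM1 or TAM7. Of the named genes, Cd81, Saa3, Fcna, Retnla and Pltp kept an adjusted p under 0.05 whichever array was left out (highest 0.017, 0.007, 0.007, 0.021 and 0.027). The 25 named genes past the test kept the sign of their means with the other coding, nearer to 0, and all lost their calls (adjusted p from 0.595 to 0.826). Within print v3p6 the calls of the alternative activation (adjusted p = 0.12), lysosome (0.12), complement (0.0727) and matrix remodelling (0.0676) lists were lost. With the other coding of both exchanged arrays, which share 1 fit, 1 of the 11 list calls was kept, that of the neutrophil list (median 1.01, adjusted p = 0.04), and the NF-kB list turned (0.16, adjusted p = 0.713). The other 9 had adjusted p-values from 0.115 to 0.969, and the median of the matrix remodelling list (0.12) and that of the complement list (-0.02) turned sign.

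In PEC, the inflammatory genes shifted as a group with LPS, while a single gene passed the test over all genes. The NF-kB and interferon genes on these 2 arrays were the basis for reading channel 2 over channel 1, so the upward direction of these lists was set by that choice. The NF-kB inflammatory list had a median log2 ratio of 2.01, with 28 of 31 members above 0 (adjusted p = 5.65e-28). Of its members, 17 rose when adjusted over the list alone. The cytokine Il1b was at 4.94 ± 2.0 (30.8-fold) and Tnf at 3.58 ± 1.94 (11.9-fold; SD, n = 2, adjusted p = 0.302 and 0.173), Nos2, the inducible nitric oxide synthase, at 3.57 ± 0.28 (SD, n = 2, adjusted p = 0.348) and Cd40, a costimulatory receptor, at 2.78 ± 0.93 (SD, n = 2, adjusted p = 0.165). The gene past the test was Tpx2, a spindle assembly factor with the Entrez identifier 72119, which was 53.3-fold higher (log2 ratio 5.74 ± 0.28, SD, n = 2; 2 of 2 arrays; adjusted p = 0.0035). This comparison gave the response of peritoneal macrophages to LPS.

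Chemokines shifted up (median 0.79, 16 of 25 members above 0, adjusted p = 6.2e-06). When adjusted over the list alone, 5 members rose. The inflammatory chemokines Ccl3 and Ccl4 were at 4.94 ± 1.86 and 4.96 ± 2.01, and the T cell attractants Ccl5 and Cxcl10 at 4.35 ± 0.21 and 4.00 ± 1.45 (SD, n = 2, adjusted p from 0.135 to 0.302). The interferon response list shifted up (median 1.01, 34 of 41 above 0, adjusted p = 4.15e-14, and 0.0602 with an estimated correlation). Adjusted over the list alone, 13 members rose. Antigen presentation genes shifted up as well. The MHC class II list had a median of 1.34 (9 of 12 above 0, adjusted p = 6.2e-06) and the MHC class I list one of 1.49 (9 of 10 above 0, adjusted p = 4.08e-05, and 0.117 with an estimated correlation). Adjusted over each list alone, 4 and 5 members rose. With an estimated correlation the NF-kB, chemokine and MHC class II lists kept their calls (adjusted p = 0.0417 for each), and they were the only list calls of any comparison to do so.

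Genes of general cell functions were also higher after LPS in PEC. The ribosomal protein list had a median of 1.82 (25 of 26 above 0, adjusted p = 2.4e-17, and 0.119 with an estimated correlation). The lysosome list had one of 0.91 (29 of 34 above 0, adjusted p = 1.17e-06, and 0.18 with an estimated correlation) and the oxidative phosphorylation list one of 0.95 (26 of 29 above 0, adjusted p = 6.2e-06, and 0.187 with an estimated correlation). That of the macrophage identity list was 0.90 (19 of 21 above 0, adjusted p = 3.08e-06, and 0.188 with an estimated correlation). Adjusted over each list alone, 12, 0, 0 and 1 members rose. The Toll-like receptor and NF-kB pathway list (median 0.83, adjusted p = 9.34e-05, and 0.093 with an estimated correlation), and the complement and Fc receptor list (0.73, adjusted p = 0.000313, and 0.119 with an estimated correlation) shifted up, with 1 and 4 members that rose when adjusted over the list alone. So did the antioxidant list (0.45, adjusted p = 0.000322, and 0.119 with an estimated correlation), the chemokine and cytokine receptor list (0.55, adjusted p = 0.000973, and 0.0602 with an estimated correlation) and the matrix remodelling list (0.13, adjusted p = 0.0021, and 0.119 with an estimated correlation), with 4, 1 and 4 such members. Examples were Mt1, a metal-binding antioxidant protein (3.44 ± 0.22), and Timp1, an inhibitor of matrix proteases (3.73 ± 0.18; SD, n = 2, adjusted p = 0.302 and 0.173).

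In PEC, 4 further list shifts depended on single arrays. The glycolysis and hypoxia list (median 0.35, adjusted p = 0.0099, and 0.166 with an estimated correlation) lost its call without PEC2 (adjusted p = 0.0861), as did the lipid handling list (0.30, adjusted p = 0.0344, and 0.166 with an estimated correlation) and the neutrophil list (0.71, adjusted p = 0.011, and 0.369 with an estimated correlation), both at 0.478. The heat shock and immediate early list (0.63, adjusted p = 0.0298, and 0.119 with an estimated correlation) lost it without PEC1 (0.0881) and without PEC2 (0.478). Adjusted over the list alone, 2 neutrophil genes rose and none of the other 3 lists. Padi4, an arginine deiminase of granulocytes, was at 6.17 ± 0.50 and Lcn2, which binds bacterial siderophores, at 3.33 ± 0.92 (SD, n = 2, adjusted p = 0.182 and 0.263). No other marker list passed the test: the peritoneal macrophage list had an adjusted p of 0.0664, the fibroblast list 0.748, and the other 6 lay between 0.33 and 0.871.

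By limma 1 gene changed and 725 had an unadjusted p under 0.05. Both arrays had the same channel order, so a gene-specific dye effect stays in the mean. The call for Tpx2 was lost with a loop fit and a dye term (4.83, adjusted p = 0.467), on the comparison's own arrays and within print v3p6, which held 1 of the 2 arrays (0 genes; 299 at an unadjusted p under 0.05). The count was 28 with a loop fit, 5 with positions removed, 3 with the arrays scaled, 2 with the other coding of the exchanged arrays or without TAM-b or TAM-2R, 85 without PEC1 and 48 without PEC2, where the lone remaining array is assumed to vary like those of the other groups. The loop fit with a dye term ended the calls of the glycolysis (adjusted p = 0.138), lipid handling (0.0722) and neutrophil (0.366) lists, and removing positions that of the neutrophil list (0.19). Print v3p6 alone ended those of the heat shock (adjusted p = 0.0972), lipid handling (0.0525) and matrix remodelling (0.0704) lists. The other coding of the exchanged arrays, which changes the estimated spread and not these means, kept 16 of the 18 list calls and lost those of the lipid handling (0.223) and matrix remodelling (0.108) lists.

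In TAM, no gene passed the test for LPS over all genes, and the inflammatory genes shifted up as a group. The NF-kB inflammatory list had a median log2 ratio of 0.97 (22 of 31 members above 0, adjusted p = 2.75e-09, and 0.567 with an estimated correlation). Of its members, 4 rose when adjusted over the list alone. Ccl5 was at 4.53 ± 0.92 (23.1-fold; SD, n = 2, adjusted p = 0.145), Ccl4 at 4.09 ± 0.75 (SD, n = 2, adjusted p = 0.828), Nos2 at 3.69 ± 2.52 (SD, n = 2, adjusted p = 0.828), Cxcl10 at 3.03 ± 1.38 (SD, n = 2, adjusted p = 0.74) and Tnf at 1.84 ± 0.56 (SD, n = 2, adjusted p = 0.828). Pnn, a nuclear protein of RNA splicing, had the smallest p of the higher genes (3.72 ± 1.29, SD, n = 2, adjusted p = 0.145), and Fut7, a fucosyltransferase, that of the lower ones (-3.01 ± 1.95, SD, n = 2, adjusted p = 0.72). This comparison gave the response of tumour macrophages to LPS.

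**Figure D3:**
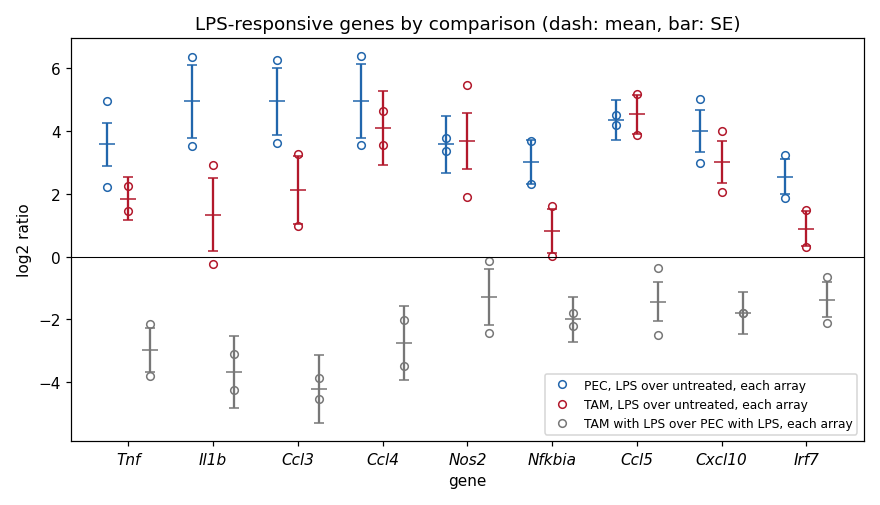
Log2 ratio (vertical axis) of 9 inflammatory and interferon genes for LPS over untreated in PEC, LPS over untreated in TAM, and TAM with LPS over PEC with LPS. Points are single arrays (2 per comparison), dashes the means and bars the standard errors; Tnf had means of 3.58, 1.84 and -2.97, and Ccl5 of 4.35, 4.53 and -1.43.

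The interferon response list shifted up in TAM with LPS (median 0.15, 25 of 41 members above 0, adjusted p = 0.000421, and 0.567 with an estimated correlation), and so did the chemokine list by its test and mean (mean 0.36, adjusted p = 0.0183, and 0.567 with an estimated correlation), although its median was -0.05. In each list 2 members rose when adjusted over the list alone. The median of the interferon list was -0.31 on TAM-trial and 0.50 on TAM-16, so its sign was not shared by both arrays. Without TAM-16 the adjusted p of the NF-kB, interferon and chemokine lists was 0.0505, 0.845 and 0.603. The ribosomal protein list shifted down (median -1.03, 23 of 26 members below 0, adjusted p = 0.000421, and 0.79 with an estimated correlation), and so did the macrophage identity list (median -0.82, 16 of 21 below 0, adjusted p = 0.0383, and 0.854 with an estimated correlation). The fibroblast and stroma list shifted up (median 0.29, 31 of 42 above 0, adjusted p = 0.0123, and 0.567 with an estimated correlation). None of these 3 had a member past the test over all genes or adjusted over the list alone, and without TAM-trial their adjusted p was 0.104, 0.19 and 0.282. Without that array the ribosomal protein and macrophage identity lists also turned up, as their medians were -2.04 and -1.24 on TAM-trial but 0.14 and 0.18 on TAM-16, so their direction was not shared by both arrays. The macrophage identity list also lost its call without TAM-2R (adjusted p = 0.0586) or TAM-3 (adjusted p = 0.0592). No other marker list passed the test (adjusted p from 0.154 to 0.966).

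By limma 0 genes changed and 497 had an unadjusted p under 0.05. A single gene passed with the arrays scaled and 3 without TAM-16, which leaves 1 array assumed to vary like the others. Print v3p6 held TAM-16 alone and gave 0 genes (84 at an unadjusted p under 0.05), and the other coding of the exchanged arrays gave 0 too (365). That coding kept 4 of the 6 list calls and lost those of the chemokine (adjusted p = 0.105) and macrophage identity (0.295) lists. Both arrays had the same channel order, and the median of all genes was -0.127, or -0.027 after each array was centred. With a loop fit and a dye term the interferon (adjusted p = 0.0587), ribosomal protein (0.304), macrophage identity (0.884) and fibroblast (0.15) lists lost their calls, and within print v3p6 the last 3 did (0.0719, 0.16 and 0.303), where the ribosomal protein and macrophage identity lists turned up. With positions removed the macrophage identity (adjusted p = 0.209) and fibroblast (0.341) lists lost theirs.

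With LPS in both, TAM and PEC differed in 6 genes or unnamed features, 1 higher and 5 lower in TAM. Fcna was 31.9-fold lower (log2 ratio -5.00 ± 0.10, SD, n = 2, adjusted p = 0.0075), the urokinase receptor Plaur 17.8-fold lower (-4.15 ± 0.62, SD, n = 2, adjusted p = 0.0075) and the phospholipid transfer protein Pltp 16.5-fold lower (-4.05 ± 0.17, SD, n = 2, adjusted p = 0.0075). Plpp3, a lipid phosphatase, fell (-3.50 ± 0.32, SD, n = 2, adjusted p = 0.0354), and 0610009E02Rik rose (4.48 ± 1.36, SD, n = 2, adjusted p = 0.0354). All 5 had the same sign on 2 of 2 arrays, which the rule for naming them required. The 2 arrays had opposite channel order. With the other coding of the exchanged array TAM1 the 5 means turned sign (Fcna 0.07, Plaur 0.44, Pltp 0.12, Plpp3 0.22 and 0610009E02Rik -0.96). Turning 1 of 2 arrays of the same sign must bring their mean nearer to 0, so this does not show which coding is right. This comparison addressed how the activated macrophages differ.

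With the coding used here, inflammatory genes were lower in TAM with LPS than in PEC with LPS. None of the 16 list calls of this comparison held with the other coding of both exchanged arrays, where the median of the NF-kB list was 0.27 (adjusted p = 0.962) and the means of Tnf and Ccl3 turned to 0.81 and 0.33. Turning 1 of 2 arrays that agree brings their mean nearer to 0, so this loss does not show which coding is right. The NF-kB inflammatory list had a median of -1.34 (30 of 31 members below 0, adjusted p = 1.86e-19, and 0.0726 with an estimated correlation), with Plaur past the test over all genes and 10 members that fell when adjusted over the list alone. Its medians were -1.50 and -1.61 on the 2 arrays. Il1b was at -3.68 ± 0.82, Ccl3 at -4.21 ± 0.47 and Tnf at -2.97 ± 1.15 (SD, n = 2, adjusted p = 0.363, 0.242 and 0.195). The interferon response list shifted down (median -1.12, 36 of 41 below 0, adjusted p = 2.7e-11, and 0.0882 with an estimated correlation), with none of its members past the test over all genes or adjusted over the list alone. The chemokine list shifted down (median -0.32, 16 of 25 below 0, adjusted p = 0.002, and 0.1 with an estimated correlation). When adjusted over the list alone, 3 members fell. Ccl9 and Ccl6, chemokines of macrophages, were at -3.38 ± 0.15 and -3.29 ± 1.24 (SD, n = 2, adjusted p = 0.0557 for both). The Toll-like receptor and NF-kB pathway list (median -0.52, adjusted p = 0.0011, and 0.103 with an estimated correlation), the chemokine and cytokine receptor list (-0.25, adjusted p = 0.0012, and 0.0889 with an estimated correlation) and the MHC class I list (-0.96, adjusted p = 0.00018, and 0.103 with an estimated correlation) shifted down too, with 0, 4 and 4 members that fell when adjusted over the list alone.

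In the same coding, the lysosome list shifted down (median -0.80, 30 of 34 below 0, adjusted p = 2.2e-12, and 0.121 with an estimated correlation). Adjusted over the list alone, 9 members fell. With the other coding of both its median was 0.35 (adjusted p = 0.111). Ctsd was at -3.29 ± 0.76 and Ctsb at -2.97 ± 0.28 (SD, n = 2, adjusted p = 0.0529 for both). The lipid handling list shifted down (median -0.47, 21 of 24 below 0, adjusted p = 1.06e-08, and 0.0726 with an estimated correlation), with Pltp past the test over all genes and 3 members that fell when adjusted over the list alone. The ribosomal protein list (median -1.03, 26 of 26 below 0, adjusted p = 3.89e-07, and 0.267 with an estimated correlation) and the oxidative phosphorylation list (-0.98, 25 of 29 below 0, adjusted p = 2.51e-07, and 0.179 with an estimated correlation) shifted down with no member past either test. The matrix remodelling list (-0.26, adjusted p = 0.000182, and 0.103 with an estimated correlation) shifted down with 2 members up and 8 down when adjusted over the list alone. The antioxidant list (-0.28, adjusted p = 0.008, and 0.252 with an estimated correlation) and the angiogenesis and growth factor list (-0.16, adjusted p = 0.0121, and 0.103 with an estimated correlation) shifted down as well, each with 1 member down. These 2 lost their calls without TAM1 (adjusted p = 0.0593 and 0.158).

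Both macrophage marker lists were lower in TAM with LPS with the coding used here. With the other coding the macrophage identity list was at 0.17 and the peritoneal macrophage list at -0.18 (adjusted p = 0.962 for both). The macrophage identity list had a median of -0.93 (16 of 21 below 0, adjusted p = 2.44e-05, and 0.282 with an estimated correlation), with the lysosomal glycoprotein Cd68 at -3.50 ± 0.25 (SD, n = 2, adjusted p = 0.199). The peritoneal macrophage list had one of -0.51 (10 of 14 below 0, adjusted p = 0.000442, and 0.282 with an estimated correlation). Adjusted over each list alone, 6 and 5 members fell. The fibroblast and stroma list shifted up (median 0.48, 31 of 42 above 0, adjusted p = 0.0483, and 0.282 with an estimated correlation), although its 1 member past the test adjusted over the list alone, S100a4, a calcium-binding protein of motile cells, was lower (-3.25 ± 0.19, SD, n = 2, adjusted p = 0.0814). It lost its call without TAM1 (adjusted p = 0.0522), TAM7 (0.296), TAM-trial or TAM-16 (0.0692 each), within print v3p6 (0.522) and with positions removed (0.0752). No other marker list passed the test (adjusted p from 0.0709 to 0.844).

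By limma 6 passed and 801 had an unadjusted p under 0.05. The count was 137 with a loop fit, 131 with a loop fit and a dye term, 81 with the arrays scaled and 16 with positions removed. It was 0 with a dye term for each print, on the comparison's own arrays, with the other coding of the exchanged arrays and within print v3p6, which held TAM1 alone (294 at an unadjusted p under 0.05, and 140 with the other coding). It was 11 without TAM-2R, 4 without TAM-8 and 3 without any 1 of TAM1, PEC1, PEC2, TAM-trial or TAM-16. None of the named genes kept its call whichever array was left out (highest adjusted p of Fcna, Plaur and Pltp 0.162).

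**Figure D4:**
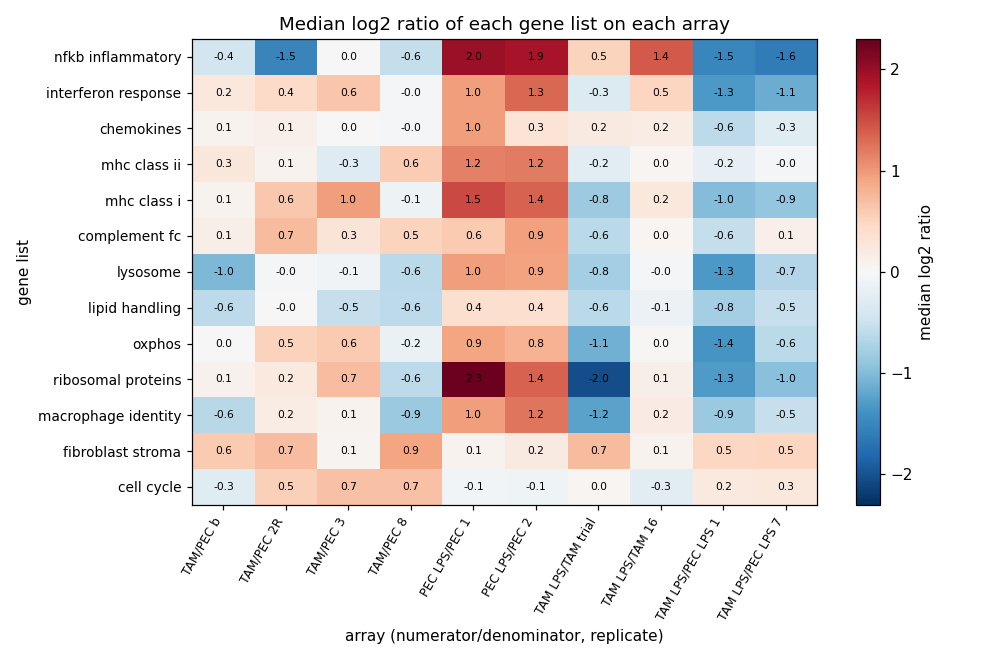
Median log2 ratio (colour scale) of 13 gene lists (vertical axis) on each of the 10 arrays (horizontal axis), grouped by comparison and turned so that the first-named condition is the numerator. The NF-kB list was at 1.98 and 1.90 on the 2 arrays of LPS in PEC and at 0.50 and 1.42 on those of LPS in TAM.

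The LPS responses of TAM and PEC were compared directly as the difference of their mean log2 ratios. No gene passed this test by limma (612 at an unadjusted p under 0.05; 199 within print v3p6 and 317 with the other coding of the exchanged arrays, where 0 passed). The difference was -4.92 ± 0.69 for Tpx2 and -3.60 ± 1.63 for Il1b (SE, limma adjusted p = 0.297 and 0.724). It was -1.73 ± 0.97 for Tnf and 0.18 ± 0.89 for Ccl5 (SE, limma adjusted p = 0.796 and 0.998). Each difference rested on 4 arrays, while its SE came from the fit on all arrays. The NF-kB inflammatory list shifted down, meaning a smaller response in TAM (median difference -0.93, 27 of 31 members below 0, adjusted p = 0.000141, and 0.235 with an estimated correlation), and none of its members passed over all genes or adjusted over the list alone. The medians of all genes differed by -0.114, or by -0.021 after each array was centred, and the NF-kB shift was larger than either.

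The ribosomal protein list differed most (median difference -2.78, 25 of 26 members below 0, adjusted p = 3.26e-21, and 0.235 with an estimated correlation). Adjusted over the list alone, 22 members passed. The macrophage identity list (-1.71, adjusted p = 8.55e-08), the oxidative phosphorylation list (-1.38, adjusted p = 1.77e-06), the lysosome list (-1.37, adjusted p = 1.77e-06) and the MHC class II list (-1.28, adjusted p = 0.000387) shifted down too (adjusted p = 0.235, 0.235, 0.235 and 0.234 with an estimated correlation), with no member past either test. Without TAM-trial the median difference was -0.58 for the NF-kB list (adjusted p = 0.042), -1.57 for the ribosomal protein list (2.57e-09), -0.99 for the macrophage identity list (0.020) and -0.71 for the oxidative phosphorylation list (0.039), and without TAM-16 it was -1.42 for the NF-kB list and -2.12 for the oxidative phosphorylation list. The other coding of the exchanged arrays kept 11 of the 12 list calls and lost that of the lipid handling list (adjusted p = 0.061). Shifts down that were lost without a single array were those of the MHC class I list (-1.60, adjusted p = 0.00076; 0.0541 without TAM-trial), the antioxidant list (-0.99, adjusted p = 0.001; 0.232 without TAM-trial) and the glycolysis and hypoxia list (-0.70, adjusted p = 0.004; 0.0852 without TAM-trial and 0.0849 with a loop fit and a dye term). Further such shifts were those of the lipid handling list (-0.84, adjusted p = 0.0024; 0.0538 without TAM-trial and 0.0986 without PEC2), the complement and Fc receptor list (-0.99, adjusted p = 0.0026; 0.257 without TAM-trial and 0.0508 without PEC2) and the interferon response list (-0.81, adjusted p = 0.003; 0.515 without TAM-trial and 0.252 without PEC2). Their adjusted p with an estimated correlation was 0.257 for the interferon list and 0.235 for the rest. Of the complement genes 4 fell adjusted over the list alone, C1qb among them (-2.60 ± 0.65, SE; adjusted p = 0.719). No other marker list passed the test (adjusted p from 0.1 to 0.851). Within print v3p6, which held 1 array of each response, the calls of the macrophage identity (adjusted p = 0.0894), oxidative phosphorylation (0.294), MHC class I (0.283), antioxidant (0.336), glycolysis (0.0809), lipid handling (0.0809), complement (0.202) and interferon (0.14) lists were lost.

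Across 8905 genes, which are not independent replicates, both responses correlated at r = 0.08, and 53.1% had the same sign. The 2 arrays of LPS in PEC correlated at only 0.269 and those of LPS in TAM at 0.096, so this value does not show how much the responses share. The count of 0 rose to 47 without PEC1, 19 without PEC2 and 1 without TAM-16, each of which leaves an arm with a lone array assumed to vary like the others.

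Of the 41 genes that differed between untreated TAM and PEC, 38 had the same sign with LPS in both, and 3 passed the test in both comparisons. The comparisons share no array but share 1 estimate of the spread of each gene. A gene with a small spread was thus favoured in both. Across all 8905 genes the log2 ratios of these comparisons correlated at r = 0.20, and 55.2% had the same sign. TAM-8 and TAM7 had the same print and channel order, and correlated at 0.568 over all features as deposited. TAM-b, TAM-2R and TAM-3 correlated with TAM7 at 0.149, 0.060 and 0.015. Part of the agreement may therefore come from the print or dyes that TAM-8 and TAM7 share, which was not tested. Each comparison holds 1 exchanged array, and the test of the coding of TAM1 assumed this agreement. When both exchanged arrays were coded the other way, 19 of the 41 had the same sign in both comparisons and 0 genes passed in both. Across all genes r was then 0.23, with 56.5% of the same sign. All 41 kept their sign untreated, but only 16 did with LPS, and Fcna, Plaur and Pltp, the 3 shared genes, were among those that turned. TAM-2R was 1 of 4 untreated arrays, but TAM1 was 1 of 2 with LPS, so recoding moved the means with LPS further. These counts therefore follow in part from the number of arrays and do not show how far the genes agree.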

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

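The tests of explanations in this part, the sign patterns included, were chosen only after the results were seen. Among the 4 arrays of untreated TAM against PEC, 43 named genes and 29 gene lists (72 items) were examined for an array far from the other 3, and 6 had one, where chance gives about 1 in 20. Retnla was at -3.18 on TAM-b against -5.88 to -5.47 on the others, and Cd5l at -0.93 on TAM-b against -5.05 to -4.44. Lpl was at -2.31 on TAM-2R against -4.51 to -4.25. The median of the lipid handling list was -0.00 on TAM-2R against -0.61 to -0.53, that of the cell cycle list -0.28 on TAM-b against 0.55 to 0.68, and that of the epithelial and mesothelial list -0.48 on TAM-3 against 0.01 to 0.09.

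The response to LPS differed between TAM and PEC for 12 lists by a test of the difference itself, with 2 arrays for each response and a lower median in TAM. The medians of the NF-kB and interferon lists were above 0 in both (2.01 and 1.01 in PEC, 0.97 and 0.15 in TAM), although that of the interferon list was -0.31 on TAM-trial and 0.50 on TAM-16. Those of the other 10 were above 0 in PEC and below 0 in TAM, where the ribosomal protein (-1.03) and macrophage identity (-0.82) lists passed the test as shifts down. All 10 were below 0 on TAM-trial, but 7 of the 10 were above 0 on TAM-16, the ribosomal protein (0.14) and macrophage identity (0.18) lists among them, and without TAM-trial these 2 turned up (adjusted p = 0.104 and 0.190). The median differences were -0.93 for NF-kB inflammatory genes, -0.81 for interferon response, -1.28 for MHC class II, -1.60 for MHC class I, -0.99 for complement and Fc receptors, -1.37 for lysosome, -0.84 for lipid handling, -0.70 for glycolysis and hypoxia, -1.38 for oxidative phosphorylation, -2.78 for ribosomal proteins, -0.99 for antioxidant genes and -1.71 for macrophage identity. None of the 12 calls held with an estimated correlation (adjusted p from 0.234 to 0.257). Without TAM-trial the adjusted p was 0.515 for interferon response, 0.0541 for MHC class I, 0.257 for complement, 0.0538 for lipid handling, 0.0852 for glycolysis and 0.232 for antioxidant genes. With a loop fit and a dye term it was 0.0849 for glycolysis. Without PEC2 it was 0.252 for interferon response, 0.0508 for complement and 0.0986 for lipid handling. The median differences that moved by over 1.5 times without TAM-trial were those of NF-kB genes (-0.58), interferon response (-0.31), MHC class I (-1.0), oxidative phosphorylation (-0.71), ribosomal proteins (-1.57), antioxidant genes (-0.50) and macrophage identity (-0.99), and without TAM-16 those of NF-kB genes (-1.42) and oxidative phosphorylation (-2.12). Without PEC2 that of interferon response did (-0.43).

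The smaller LPS response of the NF-kB list in TAM was weighed against 3 technical explanations. A gene-specific dye effect that is equal on every array would cancel here, as the 4 arrays had the same channel order. One that differs between the 3 prints would cancel within print v3p6, where the response of the list was also smaller in TAM. That rests on a lone array for each response, PEC2 and TAM-16, so such an effect stays open. On the exchanged array TAM1, in a comparison other than this difference, the list median was -1.50 with the coding used here. It was 1.5 with the other coding, against -1.61 on TAM7. A shift of abundant transcripts that is not specific to inflammation may account for part of the pattern, as the ribosomal protein list moved further (-2.78), and without TAM-trial the ribosomal list was at -1.57 and the NF-kB list at -0.58 (adjusted p = 2.57e-09 and 0.042). Without TAM-trial the median difference of the NF-kB list was still below 0, at -0.58. That value rests on TAM-16 as the lone array of LPS in TAM, so whether TAM-trial alone gave the pattern stays open. The route that leaves out both arrays of LPS in TAM does not settle it. It gave -0.93 with 28 of 31 members below 0, but -0.02 with 17 of 31 with the other coding of the exchanged arrays. The list median of an untreated array (-1.53, TAM-2R) was also as low as that of an array with LPS (-1.50, TAM1). A difference between the macrophages themselves stays among the open explanations, untested.

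Ratios followed the place of a feature within groups of 96 consecutive feature numbers, by up to 49.1% of the variance of an array (TAM-b), 33.4% (TAM-trial) and 28.8% (TAM-2R), against 0.99% by chance. Genes at these places that differ between TAM and PEC were argued against as the only source, since the profile of TAM-b correlated with those of TAM-2R, TAM-3 and TAM-8 at r = 0.17 (-0.17 with the other coding), 0.01 and 0.54 (median 0.17), and with that of TAM-trial, which holds no PEC, at 0.77. A bias of printing or hybridisation may be the source, as profiles of arrays from different comparisons correlated at up to 0.83 (TAM-8 with TAM-trial), above the highest value with shuffled positions, 0.66 in 100 shuffles. Print version alone did not sort the profiles, as TAM-b and TAM-trial, at 0.77, were of different prints and TAM7 and TAM-trial, at 0.44, of the same. TAM-8 and TAM-trial, at 0.83, were of the same print, v9p2. Over all features as deposited, the v9p2 arrays correlated at 0.568 (TAM-8 with TAM7), 0.520 (TAM-8 with TAM-trial) and 0.433 (TAM7 with TAM-trial). The highest value of any other pair was 0.379 (TAM-b with TAM-trial), so an effect of print stays open.

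The fibroblast and stroma list lay higher in untreated TAM (median 0.42, 31 of 42 members above 0, adjusted p = 0.000321, and 0.352 with an estimated correlation, or a median of 0.21 and adjusted p = 0.490 with the other coding of both exchanged arrays). Position bias as its whole source was argued against, since the list passed with positions removed (adjusted p = 0.017). Fibroblasts or mesenchymal tumour cells in the TAM harvest could give the shift, which adherence to plastic, the selection per the labels, would not remove, but their abundant transcripts left this open (median of 4 genes 1.88), with Col1a1 at 0.46 ± 1.33 (2 of 4 arrays above 0), Col1a2 at 1.68 ± 3.72 (3 of 4), Sparc at 4.23 ± 3.46 (4 of 4) and Bgn at 2.07 ± 0.38 (4 of 4; SD, n = 4). A lower share of macrophages, which would raise all other cell types alike, stays open too, as the fibroblast list exceeded the endothelial list by 0.56 ± 0.51 (SD, n = 4, 4 of 4 arrays above 0). Of the 42 measured members 2 were in another list, how many macrophages express could not be told from ratios, and higher expression by the TAM themselves was not tested.

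Turning the sign of arrays of untreated TAM against PEC gives 8 patterns, too few for a share under 0.05. The real pattern was the 1 pattern with as many genes, 41, and the highest of the others had 0. With positions removed 33 genes passed, 26 of them among the 41. The count of 41 was 6 without TAM-8, 13 without TAM-2R, 19 without TAM-3, 23 without TAM-b, 24 without TAM-trial or TAM-16, and 14 without any 1 of PEC1, PEC2, TAM1 or TAM7.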

How the results depend on the processing

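The alternatives on feature position and the gene lists with the other coding of the exchanged arrays were chosen only after the data were seen; the rest were planned. Robust eBayes, an added minimum log2 ratio of 1 and both filters on missing values left the counts as they were, the filters because no value was missing. No paired analysis was possible because the groups share fewer than 2 replicate labels. Signal over background could not be examined, since only ratios were used, and LPS in PEC, LPS in TAM and TAM against PEC with LPS rest on 2 arrays each. Of 31 results of named genes past the threshold, 29 kept their call with each array centred, 29 with the loop fit, 20 with the loop fit and a dye term, 21 with positions removed, 16 with a dye term in the direct fit, 15 with the arrays scaled, 6 with a dye term for each print, 2 on own arrays alone, 1 with the other coding of the exchanged arrays, where 5 turned sign, and 0 within print v3p6. Fewer arrays were used in print v3p6 and own arrays alone; the cause was not tested elsewhere. Of the 41 genes of untreated TAM against PEC, 31 were among the 45 of the loop fit, 19 among the 26 of the loop fit with a dye term and 26 among the 33 with positions removed.

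In untreated TAM against PEC (41 genes) the count was 10 with the arrays scaled, 26 with the loop fit and a dye term, 9 with a dye term for each print, 17 with a dye term in the direct fit, 2 on own arrays alone, 0 with print v3p6 alone and 0 with the other coding of the exchanged arrays, and 6 to 24 when 1 array was left out (6 without TAM-8, 24 without TAM-trial or TAM-16). For LPS in PEC (1 gene) it was 3 with the arrays scaled, 28 with the loop fit, 5 with positions removed, 2 with the other coding, 0 on own arrays alone, with print v3p6 alone, with the loop fit and either kind of dye term, and with positions removed in the loop fit with a dye term, and 1 to 85 when 1 array was left out (85 without PEC1, 48 without PEC2). For LPS in TAM (0 genes) it was 1 with the arrays scaled and 0 to 3 when 1 array was left out (3 without TAM-16). For TAM against PEC with LPS (6 genes) it was 81 with the arrays scaled, 137 with the loop fit, 131 with a dye term added, 188 with positions removed as well, 16 with positions removed, 14 with positions and groups of 96 removed, 0 with a dye term for each print, on own arrays alone, with print v3p6 alone and with the other coding, and 3 to 11 when 1 array was left out (11 without TAM-2R). The difference in LPS response (0 genes) gave 0 to 47 when 1 array was left out (47 without PEC1, 19 without PEC2).

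Of the 29 lists, 11, 18, 6, 16 and 12 passed the test in the 5 comparisons in this order. With an estimated correlation 0, 3, 0, 0 and 0 passed, and with fry 4, 12, 0, 9 and 0, a test of another hypothesis. With the other coding of the exchanged arrays 1, 16, 4, 0 and 11 passed, and where the groups hold no exchanged array this changes only the estimated spread. In TAM against PEC with LPS it turned TAM1 and not TAM7, which brings means nearer to 0 where these arrays agree. With that coding the NF-kB list turned in untreated TAM against PEC (adjusted p = 0.713). In TAM against PEC with LPS 11 lists turned, the NF-kB, matrix remodelling, angiogenesis, chemokine, lipid handling, ribosomal protein, antioxidant and macrophage identity lists with an adjusted p of 0.962, the Toll-like receptor pathway and oxidative phosphorylation lists with 0.718 and the lysosome list with 0.111. The medians of the interferon (0.03) and MHC class I (0.06) lists turned sign as well, while the direction of their tests stayed down. For LPS in TAM 2 lists passed with the loop fit and a dye term. For the difference in LPS response 5 passed with print v3p6 alone, and 6 to 14 when 1 array was left out. The direction of the ribosomal protein and macrophage identity lists for LPS in TAM turned with print v3p6 alone (adjusted p = 0.072 and 0.160). Leaving out 1 array gave an adjusted p from 2.35e-14 to 0.104 for the first and from 1.83e-05 to 0.190 for the other, and both turned without TAM-trial (0.104 and 0.190).

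Where the mean log2 ratio of a named gene turned sign, its value under that setting follows; the cause was not tested in any of them. Il12b 0.02 and Ifit1 0.01 for untreated TAM against PEC, Cxcl9 0.00 for LPS in PEC, Cxcl9 0.05 for LPS in TAM, Cxcl9 0.04 for the difference in LPS response had turned sign with each array centred. Il12b 0.07 for untreated TAM against PEC, Cxcl9 0.03 for LPS in PEC, Cxcl9 0.06 for LPS in TAM, Ccl5 -0.04 and Cxcl9 0.03 for the difference in LPS response had turned sign with the arrays scaled. Il12b 0.05, Ifit1 0.24 and Tgfb1 -0.19 for untreated TAM against PEC, Il12b 0.15, Mrc1 -0.66 and Vegfa 0.15 for LPS in PEC, Ccl2 0.09, Cxcl9 0.04, Irf7 -0.21, Mrc1 0.02 and Tgfb1 -0.49 for LPS in TAM had turned sign with the loop fit with a dye term. Vegfa 0.40 for LPS in TAM, Il12b 0.20 for TAM against PEC with LPS, Nos2 -0.28, Ccl5 -1.27, Cxcl9 0.39, Mrc1 0.68 and Vegfa 0.25 for the difference in LPS response had turned sign with the loop fit with a dye term. Il12b 0.05, Ifit1 0.48 and Tgfb1 -0.30 for untreated TAM against PEC, Il12b 1.08 and Mrc1 -1.06 for LPS in PEC, Ccl2 1.02, Irf7 -0.03, Tgfb1 -0.72 and Vegfa 0.27 for LPS in TAM, Nos2 0.23 for TAM against PEC with LPS, Il12b -0.79 for the difference in LPS response had turned sign with a dye term for each print. Ccl5 -1.50, Cxcl9 0.29, Mrc1 0.82, Vegfa 0.39 and Mmp9 -0.30 for the difference in LPS response had turned sign with a dye term for each print. Il12b 0.23, Ifit1 0.48 and Tgfb1 -0.07 for untreated TAM against PEC, Mrc1 -0.07 and Vegfa 0.33 for LPS in PEC, Ccl2 0.45, Tgfb1 -0.26 and Vegfa 0.12 for LPS in TAM had turned sign with a dye term in the direct fit. Nos2 0.23, Ccl3 0.57, Ccl4 1.22, Nfkbia 0.21 and Ccl2 -0.60 for untreated TAM against PEC, 0610009E02Rik -0.96, Tgfbi -0.29, Chil1 -0.43, Snx30 -1.24, Fcna 0.07 and Plaur 0.44 for TAM against PEC with LPS had turned sign with the other coding of the exchanged arrays. Pltp 0.12, Plpp3 0.22, Oas1a 0.03, Edn1 0.52, Ccl6 0.88, Il17ra 0.34, Psmb8 0.45, Tap1 0.06, Ctsd 0.54, Ctsb 0.20 and Cox6c 0.46 for TAM against PEC with LPS had turned sign with the other coding of the exchanged arrays. Rpl35a 0.33, Rplp2 0.53, Gstm1 0.57, Sirpa 0.17, Cd68 0.17, S100a4 0.13, Eln 0.65, Tnf 0.81, Ccl3 0.33, Ccl4 0.73 and Nfkbia 0.20 for TAM against PEC with LPS had turned sign with the other coding of the exchanged arrays. Ccl5 1.08, Cxcl10 0.01, Irf7 0.72 and Tgfb1 1.75 for TAM against PEC with LPS had turned sign with the other coding of the exchanged arrays. Ifit1 0.45 for untreated TAM against PEC, Il12b 0.07 and Cxcl9 0.20 for LPS in PEC, Rpl27a 0.16, Bgn -0.12, Il12b -0.91, Ccl2 1.52 and Mrc1 0.08 for LPS in TAM, Il12b 0.64 for TAM against PEC with LPS, Il12b -0.98 and Mmp9 -0.45 for the difference in LPS response had turned sign with print v3p6 alone. Ifit1 0.29 and Tgfb1 -0.39 for untreated TAM against PEC, Cxcl9 0.53 and Mrc1 -0.06 for LPS in PEC, Il12b -0.23 for LPS in TAM, Il12b 0.08 for TAM against PEC with LPS had turned sign with positions removed. Ifit1 0.33 and Tgfb1 -0.30 for untreated TAM against PEC, Cxcl9 0.54 for LPS in PEC, Il12b -0.24 for LPS in TAM, Il12b 0.17 for TAM against PEC with LPS, Ccl5 -0.11 for the difference in LPS response had turned sign with positions and groups of 96 removed. Ifit1 0.55, Mrc1 0.09 and Tgfb1 -0.86 for untreated TAM against PEC, Cxcl9 0.24 and Vegfa 0.01 for LPS in PEC, Ccl2 0.61, Irf7 -0.42, Mrc1 0.29, Tgfb1 -0.81 and Vegfa 0.34 for LPS in TAM, Il12b 0.08 for TAM against PEC with LPS had turned sign with positions removed in the loop fit with a dye term. Ccl5 -1.46, Mrc1 0.28 and Vegfa 0.33 for the difference in LPS response had turned sign with positions removed in the loop fit with a dye term. Mrc1 -0.30 for LPS in PEC, Il12b -0.05, Cxcl9 0.15, Ifit1 -0.09 and Mrc1 0.29 for LPS in TAM, Il12b 0.14 for TAM against PEC with LPS, Nos2 -0.29, Ccl5 -1.55, Cxcl9 0.35, Mrc1 0.59 and Vegfa 0.39 for the difference in LPS response had turned sign with the loop fit. Vegfa 0.11 for LPS in PEC had turned sign with its first feature alone. Vegfa 0.24 for the difference in LPS response had turned sign with its other feature alone.

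Il1b from -0.07 to 1.51, Il12b from -0.26 to 0.37, Ccl4 from -1.84 to 0.06 and Ifit1 from -0.54 to 0.45 ranged across 0 for untreated TAM against PEC when 1 array was left out. Il12b from -1.17 to 0.07, Cxcl9 from -0.21 to 0.20, Vegfa from -0.34 to 0.13 and Mmp9 from -0.67 to 0.76 ranged across 0 for LPS in PEC when 1 array was left out. Rpl27a from -3.41 to 0.16, Bgn from -0.12 to 2.62, Il1b from -0.23 to 2.91, Il12b from -0.91 to 1.28, Ccl2 from -3.40 to 1.52 and Cxcl9 from -0.11 to 0.00 ranged across 0 for LPS in TAM when 1 array was left out. Ifit1 from -0.93 to 1.28 and Mrc1 from -0.87 to 0.08 ranged across 0 for LPS in TAM when 1 array was left out. Il12b from -0.82 to 0.64 and Tgfb1 from -3.11 to 0.39 ranged across 0 for TAM against PEC with LPS when 1 array was left out. Il12b from -0.36 to 1.83, Nos2 from -1.67 to 1.89, Ccl4 from -2.29 to 0.55, Ccl5 from -0.47 to 0.83, Cxcl9 from -0.25 to 0.15 and Cxcl10 from -2.0 to 0.05 ranged across 0 for the difference in LPS response when 1 array was left out. Tgfb1 from -1.61 to 0.39, Vegfa from -0.44 to 0.03 and Mmp9 from -0.10 to 1.34 ranged across 0 for the difference in LPS response when 1 array was left out.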

Other observations

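The correlation tests in this part were chosen only after the results were seen. A hypothesis is that the interferon genes that LPS moves most in PEC are those that differ most in untreated TAM. Across the 41 genes of the interferon list, the mean log2 ratios of LPS in PEC (2 arrays) and of untreated TAM against PEC (4 arrays) correlated at Pearson r = 0.43 and Spearman rho = 0.33 (permutation p of r = 0.005, 100000 resamples). Both ratios have untreated PEC as the denominator, which by itself favours a positive correlation, so this test leaves the hypothesis open. Random sets of 41 genes gave r from -0.34 to 0.42 (95% of 1000 sets), and that range does not allow for interferon genes moving together in PEC. LPS in TAM, a ratio without PEC that shares untreated TAM, correlated with untreated TAM against PEC at r = 0.54 across the list. No range of random sets is given for this value. Over all features as deposited, TAM-trial correlated with TAM-b at 0.379 and TAM-8 at 0.520, but with TAM-2R at 0.011 and TAM-3 at -0.053. TAM-16 correlated with these 4 arrays at 0.023 to 0.165. The value of 0.54 may therefore not be particular to the list. The genes of the list are not independent replicates, so the permutation p does not measure how arrays vary. The correlation of LPS in PEC with untreated TAM against PEC was r = 0.50 with positions removed and r = 0.06 over all 8905 genes and features. With the other coding of TAM-2R it was r = 0.42. On the exchanged array TAM-2R alone r was 0.20, so a dye effect shared by both comparisons may account for part of it. The upward shift of the list in untreated TAM was itself lost without TAM-3 (adjusted p = 0.0701), with an estimated correlation (adjusted p = 0.525) and with the other coding (adjusted p = 0.819).

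Among lists that did not pass their test, the median, mean and test differed in sign in each comparison. In untreated TAM against PEC these were angiogenesis, chemokines, chemokine and cytokine receptors, glycolysis, endothelial cells, and T and NK cells. For LPS in PEC they were endothelial cells, B and plasma cells, and mast cells and eosinophils. For LPS in TAM they were matrix remodelling, angiogenesis, alternative activation, and mast cells and eosinophils. For TAM against PEC with LPS they were B and plasma cells, erythroid cells and platelets, glycolysis and endothelial cells. For the difference in LPS response they were endothelial cells, B and plasma cells, erythroid cells and platelets, cell cycle, epithelial cells, and mast cells and eosinophils.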
